A study of Mus musculus with 6 samples.

How the data were processed

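Total RNA from NIH-3T3 cells, a mouse embryo fibroblast line kept in DMEM with fetal bovine serum, was extracted with TRIzol and made into libraries with the NEBNext Ultra RNA kit, per the labels' protocols. Of the 6 libraries, 3 came from cells on standard plates and 3 from cells on the Nanopore #3 scaffold. Groups and replicate numbers were taken from the sample labels. The labels do not say what the scaffold is made of, how long the cells were cultured, whether the replicates were separate cultures or whether strand was used in counting.

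Per the submitters' processing notes, fastp, HISAT2, HTSeq and DESeq2 were used, and the build GRCm39 is named; versions and roles are not given in the sources used here. The authors deposited a table per group with the same 581 genes, named as a table of differentially expressed genes, so every gene had passed the authors' own selection on these libraries. The deposited values are a normalised signal: read counts per gene divided by a size factor per library. The table names call the values FPKM, but in each library 100% of the values were whole multiples of a fixed step, within 0.01 read, whatever the gene length, which FPKM values would not be. The value of a gene was therefore not corrected for its length, and levels of different genes cannot be compared as molecule numbers. The steps gave size factors of 1.09, 0.972 and 1.05 for the plate libraries and 0.972, 0.944 and 1.01 for the scaffold libraries. For scaffold replicate 3 a preset check did not accept the reads as recovered, because its step of 0.98987 lay close to 1. Its values were nonetheless whole multiples of that step. The reads of this library entered no count test and no ratio of reads. Library totals and genes outside the selection were not analysed here, so the deposited scaling was not checked against the whole libraries. The normalised totals over the 581 genes were 269580, 271850 and 272960 on plates and 296600, 292880 and 285960 on the scaffold, and the 10 most abundant genes took 47.2% to 47.5% and 40.2% to 41.1% of them. No column of values was left out.

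Gene identifiers, positions and symbols came from the table. Of the 581 identifiers, all were found in GENCODE M21, an annotation of GRCm38. There, 555 had the same start and end as in the table and 575 the same symbol, so the coordinates are printed as GRCm38 coordinates although the processing notes name GRCm39. Exon overlaps and the strands stated with them were taken from that annotation. Gene classes, and overlaps between the spans of genes in the table, came from the table. Where a gene shares exon sequence with another, reads on the shared part cannot be assigned without knowledge of strand or of the counting mode.

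Because the values are not whole counts, the test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with a moderated test, an intensity trend and no block, two-sided, on genes with a mean value of at least 0.5, which removed none. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. The design had been written for FPKM values and was kept with the unit the values turned out to have. An exact permutation test of 3 against 3 libraries cannot give a p under 0.1, so no such test is reported per gene. Means and SDs are of the normalised values, and folds stated as fold are ratios of group means. For named genes with 1 to 3 reads in a group over the other 5 libraries, reads were obtained by multiplying each value by its library's size factor, and the ratio of summed reads, divided by the summed size factors, is given with a 95% exact interval, which covers counting error only.

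Named genes were chosen by a rule fixed before the data were examined: among genes past the threshold with separated groups, a mean of at least 5 in the higher group and an established symbol, the 12 with the largest increase and the 12 with the largest decrease, and for each list up to 4 members past the threshold with the largest absolute change. This named 71 genes. Further list members are mentioned where a list is described, 1 member of the growth factor list is not reported here or drawn in the figure of the lists although it stayed in that list's test and counts, and genes chosen after their values were seen are marked as such. The 30 gene lists covered matrix, contractile, signalling, metabolic, stress and cell type marker genes. Lists with at least 5 members in the table were tested with camera (limma) at a preset correlation of 0.01, adjusted over the 8 lists tested. Since the table holds only selected genes, camera compares a list with other selected genes and not with the transcriptome.

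Alternatives were pseudocounts of 0.1 and 0.01, no filter or a mean of at least 5, libraries rescaled to equal medians, quantile normalisation, the replicate number as a block, no trend, a 2-fold minimum, leaving out each library, and for lists an estimated correlation, fry and Fisher's exact test of direction. Added after seeing the data were the Holm adjustment, lists tested among protein-coding genes only, and a quasi-likelihood count test in edgeR 4.0.16 on the whole reads recovered from 5 libraries with the deposited size factors as offsets. That count test called 580 genes, 578 of them also called by limma. The limma step was tested on simulated counts for the 581 genes of this comparison with 200 changed, over 20 runs: it called 86.0% of genes changed by a log2 fold of 1, 99.4% of those changed by 2 and 1.42% of unchanged genes. On a simulated list of 8 genes, all raised among unchanged genes, camera found the changed list in 50 of 50 runs and called the unchanged list in 0. Each simulation left most genes unchanged and used the same small spread (dispersion 0.00316) in both groups. In the real table nearly every gene changed, and relative to the mean the scaffold libraries spread more in the lower genes. These rates therefore need not hold there. Replicates were compared before averaging, by the chi-square per degree of freedom between the normalised values of libraries of a group. It was 1.88 to 2.43 between plate libraries and 3.82 to 13 between scaffold libraries, so no pair lay within sampling noise. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for reading the tables, intervals and plots.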

Results

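RNA sequencing compared NIH-3T3 cells, an immortalised mouse embryo fibroblast line, grown on standard culture plates with the same cells grown on a scaffold that the labels call Nanopore #3. The question the series states is how this scaffold affects gene expression in fibroblasts. There were 3 plate libraries and 3 scaffold libraries. The table analysed here held 581 genes that the authors had already selected as differentially expressed on these 6 libraries, each with a normalised read count per library. The smallest difference between group means in the table was 1.00 on the log2 scale, so genes that changed by less than about 2-fold were not analysed here. Over these 581 genes the plate libraries held 293198, 264178 and 286796 reads, and scaffold replicates 1 and 2 held 288435 and 276519. The reads of scaffold replicate 3 were not counted, because a preset check of its scaling step did not accept them. The size factors that had scaled the counts ran from 0.944 to 1.09. The mean value per gene over the 6 libraries ranged from 4.49 to 28618.1, with a median of 42.5. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

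Over these genes the libraries lay apart by culture surface, which the selection of the genes on the same libraries builds in. Pearson correlations of log2 values across genes were 0.981 in every pair of plate libraries, 0.969 to 0.976 between scaffold libraries and 0.804 to 0.866 between the groups. The first principal component held 85.6% of the variance. Plate libraries lay at -18.65, -20.56 and -18.95 on it. Scaffold replicate 1 lay nearest to them at 15.25, with replicates 2 and 3 at 19.89 and 23.01.

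On the scaffold, the abundant type I collagen mRNAs fell, while Ptgs2, Angptl4, Egr1 and most of the immediate early, growth factor and matrix protease genes in the table rose. Col1a1, which encodes a chain of type I collagen, went from 18208 ± 572 on plates to 7400 ± 1140 on the scaffold (mean ± SD, n = 3 each). Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, went from 4346 ± 24.7 to 15706 ± 715 (3.61-fold). Angptl4, a secreted inhibitor of lipoprotein lipase, went from 2930 ± 47.5 to 15577 ± 756 (5.32-fold). Of the 581 genes, 579 passed an adjusted p of 0.05 in limma on log2(value + 1), 187 higher and 392 lower on the scaffold. The values of the groups did not overlap in 573 genes (98.6%), where chance gives 10%. The median log2 fold change was 1.39 in the higher genes and -1.38 in the lower genes. Because the study chose these genes on the same libraries, neither the counts nor the p-values are independent evidence of a difference. The share of called genes that were lower changed with the scaling used. As deposited, 67.7% of the called genes were lower. The share was 52.4% after rescaling the libraries to equal medians and 52.9% after quantile normalisation. Both rescalings used only these selected genes, most of which fell, so they cannot test the deposited scaling. Those rescalings moved the median log2 fold change of all genes by 0.73 and 0.63, and no called gene changed sign.

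**Figure D1:**
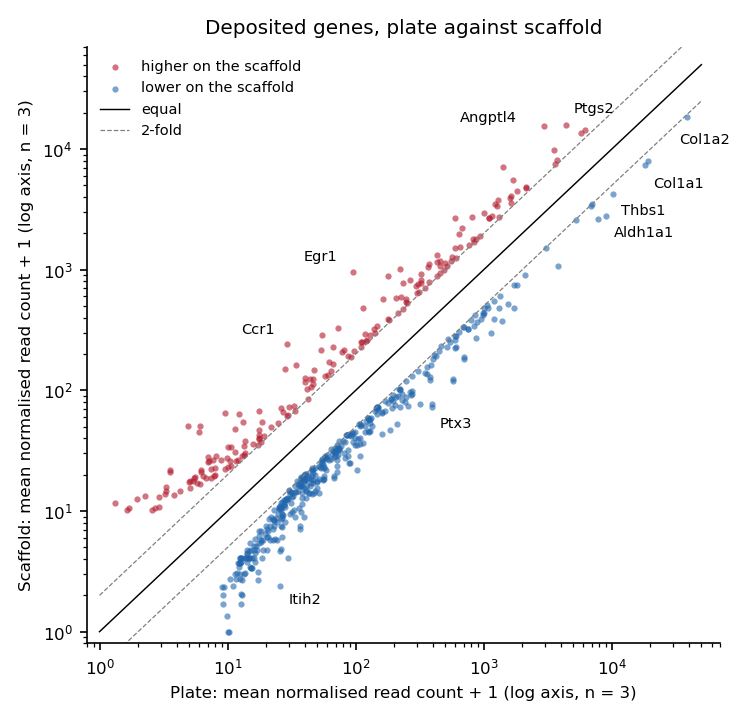
Mean normalised read count + 1 of each of the 581 genes in the 3 plate libraries (x axis) and the 3 scaffold libraries (y axis), both on log axes. The solid line marks equal values and the dashed lines 2-fold. The 189 red genes were higher on the scaffold, 187 of them past the test, and the 392 blue genes were lower, with Col1a2 at the highest mean value.

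The 12 named genes with the largest increases ranged from a transcription factor to secreted enzymes and receptors. Egr1, an immediate early zinc finger transcription factor (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984, GRCm38 coordinates), rose from 94.5 ± 8.27 to 957 ± 353, a log2 fold change of 3.26 (SE 0.234, adjusted p = 1.81e-06). Ccr1, a chemokine receptor (chromosome 9, 123962124 to 123968692), rose from 28.2 ± 5.35 to 240 ± 32.4 (log2 fold change 3.06, SE 0.194, adjusted p = 8.78e-07). The matrix metalloproteinases Mmp13 and Mmp10 rose from 2.55 ± 0.983 to 20.7 ± 4.52 and from 53.1 ± 15.8 to 285 ± 32.9. Chrna1, a muscle-type acetylcholine receptor subunit, rose from 26.9 ± 7.02 to 150 ± 29.2, and Padi2, a peptidylarginine deiminase, from 8.50 ± 4.42 to 64.0 ± 17.1. Clip4 rose from 5.08 ± 1.76 to 49.96 ± 20.8, and the non-coding transcript Stamos from 11.3 ± 1.53 to 63.0 ± 21.1. Angptl4 had the smallest standard error of the 12, with a log2 fold change of 2.41 (SE 0.0563, adjusted p = 2.92e-09).

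The remaining 3 of the 12, like Mmp13, Clip4 and Padi2, rested on few plate reads. P2ry12, a purinergic receptor, rose from 2.52 ± 1.36 to 20.1 ± 9.91, while Med12l, named here because P2ry12 lies within its span on the opposite strand, fell from 24.9 ± 5.66 to 6.53 ± 1.79. Over the 5 libraries with recovered whole reads, Cyp2j12, a cytochrome P450, had 3 reads in the 3 plate libraries and 17 in scaffold replicates 1 and 2. That is a normalised plate to scaffold ratio of 0.109 (95% interval 0.0204 to 0.376, counting error only). Without plate replicate 3 its log2 fold change was 3.58 in place of 2.93. Csf3, the granulocyte colony-stimulating factor, went from 6.19 ± 5.45 to 24.95 ± 4.78 (log2 fold change 2.44, SE 0.798, adjusted p = 0.0132), and single libraries set this value: it was 1.33 without plate replicate 3 and 3.07 without plate replicate 2. A pseudocount of 0.01 in place of 1 ended its call at a log2 fold change of 4.70, and gave 7.37 for Cyp2j12, so the pseudocount sets the size of these changes.

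Among the 12 named genes with the largest decreases, 4 were of moderate abundance. Ptx3, a secreted pattern recognition protein, fell from 390 ± 13.8 to 71.5 ± 61.9 (log2 fold change -2.82, SE 0.515, adjusted p = 0.000718). Its log2 fold change was -3.49 without scaffold replicate 1 and -2.17 without scaffold replicate 3, and -2.01 in the edgeR count test on 5 libraries. Clu, the secreted chaperone clusterin, fell from 394 ± 32.8 to 76.2 ± 40.6 (5.18-fold lower, adjusted p = 6.85e-05). Tmem119, a membrane protein known from bone-forming cells and microglia, fell from 576 ± 34.5 to 119 ± 59.8. Daam2, a formin linked to Wnt signalling, fell from 572 ± 10.3 to 122 ± 69.5. For all 4 the scaffold SD exceeded the plate SD.

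The other 8 were low genes. Itih2, a hyaluronan-binding serum protein (chromosome 2, 10094593 to 10131396), fell from 24.7 ± 7.21 to 1.41 ± 2.45, with a log2 fold change of -3.85 that became -4.64 without scaffold replicate 2. Eppk1, a plakin-family cytolinker, fell from 28.5 ± 4.42 to 3.07 ± 1.78. Steap4, a metalloreductase, fell from 14.1 ± 4.28 to 2.40 ± 4.16, with a log2 fold change of -2.87 that became -3.88 without scaffold replicate 1 and -1.92 in the count test. Nanp, a phosphatase of sialic acid synthesis, fell from 16.3 ± 13.9 to 1.70 ± 0.555 (normalised ratio of recovered reads 10.7, 95% interval 3.46 to 53.5), and its log2 fold change of -2.40 became -1.77 without plate replicate 1. Gdf5, a BMP-family growth factor, had 37 plate reads and 2 reads in scaffold replicates 1 and 2 (normalised ratio 11.4, 95% interval 2.94 to 97.6). Of its exon length, 40.3% is shared with Gm15557 on the opposite strand, and strand-aware counting is not stated, so its reads are uncertain. Over the same libraries, the amino acid transporter gene Slc7a15 had 36 and 2 reads (ratio 11.1, interval 2.86 to 95.1), and Clca1 had 37 and 2, as Gdf5 did. Olfr1189, an olfactory receptor gene, had 28 plate reads and was listed at 0 in all 3 scaffold libraries, so no fold is given. The pseudocount also moved changes of these genes: with 0.01 in place of 1, the log2 fold change went to -8.32 for Itih2, to -7.26 for Steap4, from -3.04 to -7.53 for Clca1, from -2.60 to -5.17 for Slc7a15 and from -2.66 to -3.51 for Gdf5. The count test gave -3.30 for Nanp, -3.33 for Slc7a15 and -3.36 for Gdf5. Quantile normalisation ended the calls of Steap4, Nanp and Slc7a15.

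**Figure D2:**
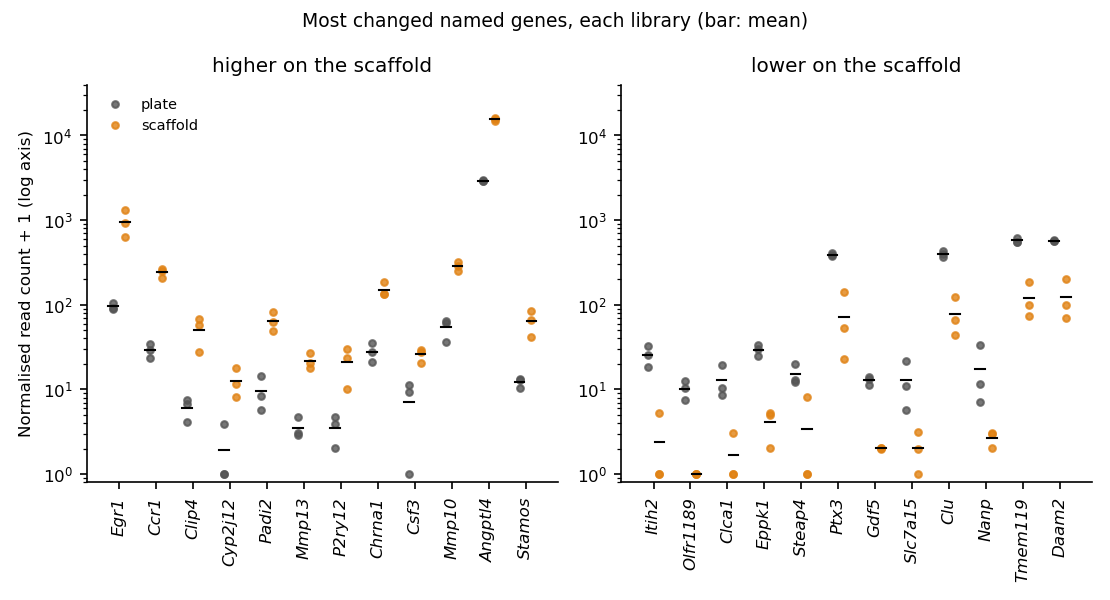
Normalised read count + 1 (log axis) of the 12 named genes with the largest increases (left) and the 12 with the largest decreases (right), each point a library (grey, plate; orange, scaffold; n = 3 each) and each bar the group mean. Angptl4 shows the tightest groups, Egr1 rises from 94.5 to 957, and the scaffold libraries spread widely for Ptx3, Clu, Tmem119 and Daam2.

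Structural matrix genes in the table were all lower on the scaffold. The table held 4 of 22 collagen symbols, 2 of 24 for collagen processing, 5 of 40 for non-collagen matrix and 3 of 31 contractile symbols. Most symbols of these lists were thus not in it, and 67.7% of all called genes were lower. The 4 collagens present fell: Col1a1 (chromosome 11, 94936224 to 94953042) by 1.31 on the log2 scale (SE 0.0939, adjusted p = 1.81e-06), Col1a2 from 38736 ± 128 to 18500 ± 2752 (adjusted p = 3.70e-06), Col12a1 from 184 ± 22.7 to 45.8 ± 26.1 and Col11a1 from 80.3 ± 9.10 to 29.4 ± 5.86. Col1a2 had the highest value of the 581 genes in every library, so quantile normalisation set its difference to 0 by construction and ended its call. Equal medians, which shift every gene alike, took its log2 fold change from -1.08 to -0.34 and that of Col1a1 from -1.31 to -0.58, and both calls remained. Both genes present from the collagen processing list were lower: Adamts2, the procollagen N-proteinase, from 591 ± 2.21 to 261 ± 57.2, and P4ha3, a prolyl hydroxylase subunit, from 88.1 ± 15.5 to 42.7 ± 2.20. All 5 non-collagen matrix genes fell, with a median log2 fold change of -1.28. Thbs1, the matricellular protein thrombospondin-1, fell from 10122 ± 334 to 4203 ± 642, the microfibril-associated Mfap5 from 942 ± 57.2 to 390 ± 55.2, and the laminin chain gene Lama5 from 72.2 ± 10.4 to 31.1 ± 4.66. Ogn, the proteoglycan osteoglycin, fell from 114 ± 23.6 to 35.4 ± 27.7, with a log2 fold change of -1.91 that became -2.50 without scaffold replicate 1 and -1.31 in the count test. Against the other selected genes, most of which also fell, this list did not stand out (camera adjusted p = 0.109). The 3 contractile genes present fell as well: Myl9, a regulatory myosin light chain, from 25.8 ± 1.73 to 6.44 ± 2.83, Synpo2 from 24.4 ± 1.11 to 9.99 ± 3.57, and Acta2, the smooth muscle actin of myofibroblasts, from 146 ± 16.9 to 69.6 ± 19.1. Both rescalings ended the calls of P4ha3, Lama5, Lama2 and Synpo2, and equal medians also that of Acta2. From the integrin and focal adhesion list, Itgb3, the integrin beta 3 subunit, rose from 205 ± 14.2 to 585 ± 74.4, and Cav1, the caveolae protein caveolin-1, fell from 5208 ± 80.3 to 2579 ± 343.

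Matrix proteases went mainly the other way, with 5 of 7 members higher and 2 lower (median log2 fold change 1.52, camera adjusted p = 0.0316, and adjusted p = 0.193 with an estimated correlation). Plau, the urokinase plasminogen activator, rose from 222 ± 15.1 to 1011 ± 80.4, and Plaur, its cell surface receptor and not itself a protease, from 1233 ± 50.1 to 3531 ± 196 (log2 fold change 1.52, and 0.80 under quantile normalisation). Mmp13, Mmp10 and Mmp3 also rose. The aggrecanase Adamts5 fell from 1724 ± 93.8 to 752 ± 192, and Mmp19 from 789 ± 6.40 to 384 ± 39.5. Without scaffold replicate 1 the call of this list ended (adjusted p = 0.0533).

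Immediate early genes and targets of serum response factor formed the list with the smallest p. Of 8 members, 7 rose and 1 fell (median log2 fold change 1.60, camera adjusted p = 0.000715, and adjusted p = 0.121 with an estimated correlation). Beside Egr1, the increases included Dusp5, a phosphatase of the MAP kinase ERK, from 600 ± 22.7 to 2704 ± 54.2 (4.50-fold), Egr3 from 113 ± 11.8 to 481 ± 35.5 and Ier3 from 1679 ± 118 to 5522 ± 52.6. Of the exon length of Dusp5, 22.1% is shared with an opposite-strand gene. Fosb, Dusp6 and Egr2 rose by 1.49, 1.19 and 1.17 on the log2 scale, and quantile normalisation took Dusp6 to 0.59 and Egr2 to 1.83. The nuclear receptor gene Nr4a3 fell from 22.0 ± 3.97 to 7.25 ± 3.71, a call that both rescalings ended.

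Growth factor genes and inflammatory mediators showed the same 5 to 2 balance. In the growth factor and angiogenic list (camera adjusted p = 0.0299, and adjusted p = 0.193 with an estimated correlation), the EGF receptor ligands Hbegf and Ereg rose from 233 ± 13.6 to 779 ± 17.3 and from 644 ± 32.1 to 1973 ± 143. Fgf2 rose with them from 247 ± 21.7 to 534 ± 37.4, as did Angptl4. Angpt1, the angiopoietin that activates the Tie2 receptor, fell from 346 ± 6.76 to 139 ± 22.5, with 14.2% of its exon length shared with an opposite-strand gene, and Vegfd fell from 419 ± 9.64 to 192 ± 20.6. In the chemokine and cytokine list (median log2 fold change 1.26, camera adjusted p = 0.0299, and adjusted p = 0.193 with an estimated correlation), Lif, an interleukin-6 family cytokine, rose from 320 ± 3.82 to 918 ± 37.5, Il11 from 43.8 ± 10.3 to 105 ± 15.3 and the monocyte chemoattractant Ccl2 from 1644 ± 114 to 3588 ± 98.4. Quantile normalisation took the log2 fold change of Ccl2 from 1.13 to 0.28 and that of Il11 from 1.26 to 1.90. Ptgs2, an enzyme and not a cytokine, had the smallest adjusted p of the list (8.62e-09). Il18 fell from 47.2 ± 19.3 to 18.9 ± 3.92 and Cxcl12 from 35.4 ± 1.91 to 15.1 ± 1.80, and both rescalings ended these calls.

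In the sterol and fatty acid list, 4 enzymes of cholesterol synthesis rose and 1 gene fell (median log2 fold change 1.11, camera adjusted p = 0.0299, and adjusted p = 0.195 with an estimated correlation). Lanosterol synthase Lss rose from 2135 ± 57.6 to 4771 ± 37.9, Msmo1 from 3747 ± 216 to 8071 ± 357, Nsdhl from 871 ± 32.9 to 1791 ± 57.9 and the farnesyl diphosphate synthase gene Fdps from 128 ± 17.9 to 288 ± 16.9. Of the exon length of Fdps, 26.7% is shared with a gene on the same strand. The gene that fell was Abca1, a cholesterol exporter and not a synthesis enzyme, from 101 ± 4.57 to 20.9 ± 6.94 (4.85-fold lower).

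All 5 interferon response genes present were lower (median log2 fold change -1.27), but the list was not set apart from the other selected genes (camera adjusted p = 0.199). Oasl2 fell from 10.0 ± 2.32 to 1.38 ± 0.641 (normalised ratio of recovered reads 6.37, 95% interval 1.99 to 32.6; log2 fold change -2.22, and -2.92 with a pseudocount of 0.01), Usp18 from 23.4 ± 6.999 to 7.11 ± 3.41, Psmb9 from 73.7 ± 5.98 to 30.9 ± 8.84, and Xaf1 from 44.9 ± 9.21 to 20.7 ± 9.92. Tap1, which overlaps Psmb9, fell too. Both rescalings ended the calls of Usp18, Psmb9 and Xaf1, and equal medians also that of Tap1. The TGF-beta and BMP list was divided, with 3 members higher and 3 lower. Its median log2 fold change was -0.09, while camera put it upward (adjusted p = 0.287). Id4 rose from 25.9 ± 5.48 to 65.4 ± 10.1 and the inhibin subunit Inhba from 498 ± 21.6 to 1133 ± 114, Pmepa1 rose by 1.05 on the log2 scale, and Id3 fell from 362 ± 35.7 to 155 ± 32.8. Tgfbi fell from 23.7 ± 7.09 to 8.49 ± 3.00. Smad9, a BMP signal transducer, fell from 25.4 ± 1.09 to 7.67 ± 6.93, with a log2 fold change of -2.05 that became -2.71 without scaffold replicate 2 and -1.21 without scaffold replicate 3, and -1.20 in the count test. Both rescalings ended the calls of Tgfbi and Smad9.

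Other lists had 1 or 2 members in the table. Of the p53 targets, Plk3 rose from 1106 ± 50.3 to 2704 ± 91.5 (log2 fold change 1.29, and 0.65 under quantile normalisation) and the death receptor gene Fas fell from 46.9 ± 2.51 to 21.5 ± 5.42. The Wnt-pathway transcription factor gene Tcf7 fell from 22.8 ± 7.52 to 7.79 ± 3.59, and the hypoxia-responsive carbonic anhydrase gene Car9 from 20.4 ± 7.05 to 4.77 ± 1.497. Both rescalings ended the calls of Fas and Tcf7. Listed markers of other cell types that were present all rose, but few were present. They were 1 of 24 macrophage and leukocyte, 1 of 17 epithelial, 1 of 17 cartilage and bone and 2 of 21 muscle and neural symbols. Mrc1, the macrophage mannose receptor, rose from 38.9 ± 8.63 to 126 ± 22.6, and the epithelial keratin gene Krt8 from 14.7 ± 2.38 to 34.8 ± 4.35. The cartilage transcription factor gene Sox9 rose from 1595 ± 18.6 to 3949 ± 162. The cardiac troponin gene Tnnt2 rose from 17.6 ± 11.2 to 53.6 ± 18.9, and the neuronal tubulin gene Tubb3 from 248 ± 11.7 to 571 ± 23.1. Tmem119, described above and on none of these lists, fell. No gene of the lists for YAP and TAZ targets, cell cycle, integrated stress and unfolded protein response, oxidative stress, heat shock, lysosome and autophagy, nuclear oxidative phosphorylation, mitochondrially encoded mRNAs and rRNAs, replication-dependent histones, endothelial cells or adipocytes was in the table, which says nothing about changes of less than about 2-fold.

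**Figure D3:**
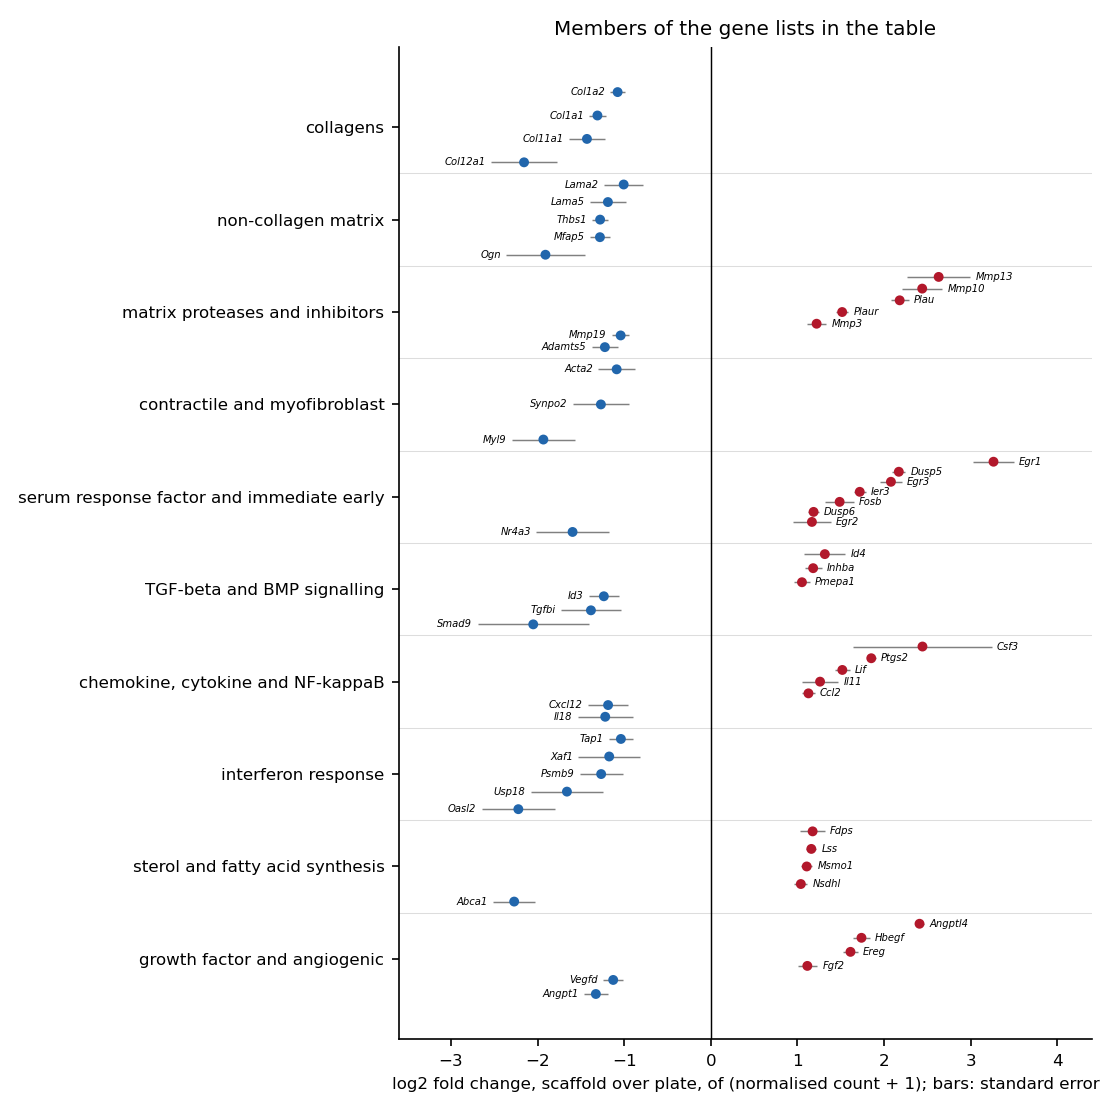
Log2 fold change (scaffold over plate, on normalised count + 1) of members of the 10 gene lists with at least 3 genes in the table, with standard errors as bars (n = 3 libraries per group; red, higher on the scaffold; blue, lower). All 4 collagens, 5 non-collagen matrix genes, 3 contractile genes and 5 interferon response genes lie below 0, while 7 of 8 immediate early genes lie above it.

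Of the 30 lists fixed before the data were examined, 19 had a member in the table. The 70 members all passed the threshold, both over all genes tested and adjusted over the list alone. The authors' selection builds this in, since 579 of the 581 genes passed, so it is no evidence for the lists. The table held 8 of 28 immediate early, 7 of 32 protease, 7 of 46 growth factor and 7 of 59 cytokine symbols. It held 5 of 37 sterol, 6 of 42 TGF-beta and BMP and 5 of 52 interferon symbols. Camera tested the 8 lists with at least 5 members against the other selected genes only, and 5 passed, all upward. None of those 5 passed with an estimated correlation. Only the immediate early list also passed under quantile normalisation, in Fisher's exact test of direction and among protein-coding genes alone. Over all alternatives except fry, which does not compare a list with other genes, its adjusted p ranged from 0.000434 to 0.121, and those of the other 4 ranged from 0.0241 to 0.195.

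By gene class, 145 of 416 protein-coding genes were higher and 271 lower. Of 98 long non-coding genes, 16 were higher and 82 lower, and of 22 pseudogenes, 14 were higher, 6 lower and 2 did not pass. Of 35 genes in the deposited TEC class of unverified transcripts, 2 were higher and 33 lower, and all 10 small RNA genes were higher. The 2 pseudogenes that did not pass, named after their values were seen, were Gm14794 (3.96 ± 2.85 on plates, 16.5 ± 15.8 on the scaffold) and H3f3c (20.9 ± 1.74 and 48.5 ± 44.0). The largest fitted log2 fold change in the table, 3.63, also belonged to a pseudogene, Gm18445, which was named for that value after it was seen. Reads of pseudogenes can come from near-identical parent genes, so these values are uncertain.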

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

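The Holm adjustment, the test of lists among protein-coding genes and the count test were chosen only after the data were seen. No called gene changed sign under any setting. The authors had selected the genes on these same libraries, at a change of about 2-fold or more. That largely builds in that calls and signs are kept, so the counts below are not independent support. Rescaling to equal medians left 189 genes higher and 208 lower, and quantile normalisation 187 and 210; of their 397 calls each, 395 and 396 were shared with the 579 reported. Equal medians centre libraries on a set in which most genes fell, which lifts every fold change by construction, while quantile normalisation moved fold changes both ways. Holm adjustment, stricter by construction, left 110 higher and 124 lower. Of the 5 lists that passed, 1 remained under quantile normalisation, 1 in Fisher's exact test of direction and 1 among protein-coding genes alone, each time the immediate early list. With an estimated correlation 0 remained. The estimate was -0.0307 for the immediate early and -0.136 for the growth factor list, below the preset 0.01. Their unadjusted camera p still rose, from 8.94e-05 to 0.0151 and from 0.0103 to 0.057. A correlation above the preset one therefore did not raise the p of these lists. The p-values of camera with an estimated correlation thus cannot be read as an effect of correlation between genes alone. The estimates for the protease, cytokine and sterol lists were 0.0398, 0.031 and 0.189. The causes were not tested further. All 8 lists passed in fry, which asks whether the genes of a list move 1 way on balance and does not compare them with other genes. Leaving out each library gave 187 to 188 genes higher, 386 to 391 lower and 4 to 5 lists, the protease list being lost without scaffold replicate 1 (adjusted p = 0.0533). The remaining settings called 567 to 580 genes. Leaving out the filter removed no gene and tests nothing. With the replicate block 188 genes were higher, 392 lower and 5 lists passed. Deviations of same-numbered libraries correlated at -0.0287, 0.0728 and 0.0576, and those of differently numbered libraries at -0.103 to 0.0337. With 3 libraries per group this cannot show whether the numbers pair the libraries. DESeq2 and TMM scaling were not run, since TMM needs whole libraries and the values are not a count table. Over 17 settings, the void filter setting included, the 71 named genes gave 1206 values, of which 1151 kept their direction and call, 55 lost the call and 0 reversed; Col1a2 under quantile normalisation, at 0, is among the 55 and kept no direction. Of the 55, 29 came with Holm, 14 with quantile normalisation, 11 with equal medians and 1, Csf3, with a pseudocount of 0.01. Depth limits the genes with under 10 reads in a group, whose fold changes depend on the pseudocount.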

Other observations

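The genes in this and the next paragraph were chosen after their values were seen, and they carry no test beyond the gene-wise limma fit of the selected table. Ptges, the inducible prostaglandin E synthase downstream of Ptgs2, rose from 3552 ± 84.1 to 9759 ± 592 (n = 3 each). Sema7a, a membrane-anchored semaphorin, rose from 1402 ± 39.0 to 7046 ± 452, a log2 fold change of 2.33 (adjusted p = 8.62e-09). Odc1, the rate-limiting enzyme of polyamine synthesis, rose from 5733 ± 166 to 13586 ± 368, and Tmsb4x, the actin-sequestering peptide thymosin beta 4, from 6201 ± 270 to 14464 ± 814. Spry2 and Dusp9, both inhibitors of signalling to ERK, rose from 549 ± 34.4 to 1183 ± 37.7 and from 212 ± 17.5 to 440 ± 22.6. Clcf1, an interleukin-6 family cytokine like Lif, rose from 1266 ± 123 to 3393 ± 216, while Osmr, the oncostatin M receptor subunit, fell from 1311 ± 24.7 to 479 ± 141.

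Aldh1a1, a retinaldehyde dehydrogenase, fell from 8995 ± 205 to 2776 ± 1291, and its close paralog Aldh1a7 from 3802 ± 82.4 to 1063 ± 520. The values of this pair are uncertain, since close paralogs share reads and an opposite-strand gene overlaps Aldh1a1. Hlf, Dbp and Per2, genes of the circadian clock or its output, fell from 869 ± 72.3 to 273 ± 96.3, from 25.3 ± 6.07 to 10.6 ± 4.35 and from 191 ± 21.9 to 70.4 ± 15.2. Dio2, which activates thyroid hormone, fell from 7795 ± 207 to 2615 ± 705, and the thioredoxin-binding protein gene Txnip from 1202 ± 42.3 to 390 ± 138. Cemip, a protein of hyaluronan breakdown, fell from 1721 ± 92.9 to 480 ± 185, while the hyaluronan synthase gene Has1 fell from 68.5 ± 17.0 to 32.4 ± 6.41. Both bradykinin receptor genes fell, Bdkrb1 from 54.2 ± 14.6 to 17.2 ± 6.38 and Bdkrb2 from 67.5 ± 17.9 to 29.8 ± 3.09. The nuclear long non-coding RNA Neat1 fell from 19014 ± 994 to 7986 ± 149.

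Of the tests below, the count over splits of the libraries and the tests of a scaling error and of plate-like RNA were chosen only after the result was seen. The Fisher's exact tests of gene classes were not among the planned tests either, so their p-values only describe these selected genes. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05; the real split gave 579 genes past the threshold and the highest other split gave 0. The authors had selected the genes on the real split, which builds in such an outcome, so it tests nothing.

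Relative to the mean, the scaffold libraries differed from each other more in lower than in higher genes. Scaffold replicate 1 lay above both others in 55.6% of the lower genes and below both in 58.8% of the higher genes. A shift by the same share of the change is larger relative to the scaffold mean in a lower gene. Relative spread therefore cannot show that the lower genes responded less evenly. Among genes with a scaffold mean of at least 100, the median coefficient of variation over scaffold libraries was 16.8% in 67 lower genes and 7.02% in 108 higher genes, a ratio of 2.39 (95% bootstrap interval 2 to 3), which argues against counting noise at low levels. A scaling error of scaffold replicate 1 would shift all genes alike, but its median log2 difference from the other scaffold libraries was 0.245 in lower and -0.125 in higher genes, a gap of 0.37 (interval 0.312 to 0.433). Plate-like RNA mixed into scaffold replicate 1 predicts the same share of the way back to the plate mean in both directions, and the median shares were 0.116 in lower and 0.131 in higher genes (difference -0.0157, interval -0.0638 to 0.0251). A mixture therefore stays open, and so does a weaker response to the scaffold of the cells behind that library, which predicts the same and was not tested separately.

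Long non-coding genes and TEC genes (an annotation class of transcripts still to be verified) were mostly lower: 115 of 133 (86.5%), against 271 of 416 protein-coding genes (65.1%; odds ratio 3.41, 95% interval 1.97 to 6.21, Fisher's exact p = 1.25e-06). Within quartiles of the mean value the common odds ratio was 2.44 (interval 1.36 to 4.57), which argues against low expression level as the whole cause. Within quartiles of gene length it was 4.65 (interval 2.6 to 8.74). Of the 123 such genes that overlap no other gene of the table, 105 were lower (85.4%, exact interval 77.9 to 91.1), which argues against reads shared with a called neighbour. DNA carry-over, unspliced RNA and reads of overlapping genes outside the table stay open as untested, and so does an effect of the scaffold on these transcripts.

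All 10 small RNA genes of the table, 66 to 191 bases long, were higher on the scaffold, against 31.3% of the other genes (Fisher's exact p = 1.13e-05; by the sign of the fold change, so the 2 genes that did not pass count as higher here and below). They include 4 mitochondrial tRNAs, among them mt-Tc (178 ± 8.19 to 390 ± 23.1) and mt-Tn (233 ± 33.3 to 468 ± 71.2), and the small nucleolar RNAs Snord49a and Snord83b. Gm22748 lies within Odc1, which also rose. Genes related in such ways are not independent, so the p overstates the evidence. A better recovery of short transcripts in general cannot be told apart from a change in these RNAs: other genes shorter than 500 bases were higher in 6 of 14 cases and longer genes in 173 of 557, an odds ratio of 1.66 (95% interval 0.468 to 5.56), and 14 genes are too few to decide. Of these 14 genes, 7 were pseudogenes, 5 of them higher, and 0 were protein-coding. The ratio thus rests largely on pseudogenes, whose reads are uncertain. No biological explanation was tested.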
